A study of Rattus rattus with 23 samples.

How the data were processed

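RNA expression was measured in nasal respiratory epithelium of male Sprague-Dawley rats on Affymetrix Rat230_2 arrays, with 1 array per animal and 23 arrays in 6 groups. Per the labels, tissue was taken by laser capture, RNA was isolated with a PicoPure kit, and it was amplified in 2 rounds with a RiboAmp OA kit and an Affymetrix labelling step before hybridization. The deposited values are intensity, the signal of each probe set on a linear scale. Their trimmed mean (2% left out at each end) was about 500 on each array, from which a scaling of each array was inferred. GCOS 1.0 is named in the labels, and its settings are not given in the sources used here. No further normalization was applied, by a rule fixed beforehand that asked for it where trimmed means differed by 1.5 times or more. That rule could not call for it here, since the trimmed means were already nearly equal. The array medians ran from 136 to 341, and results with quantile normalization and median centring are given as other settings. The precision is limited by the number of arrays.

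Values were taken as log2 of the intensity plus 16, a scale that understates the change of genes with low signals. Probe sets above the median of their own array on at least 3 arrays were kept, 19822 of 31099, and 57 control probe sets were left out of the tests. Gene symbols were those of the platform's probe table: 20832 probe sets had 1 symbol, 436 had several and 9831 had none. A gene was represented by its kept probe set with 1 symbol and the highest mean log2 value, which gave 11249 genes. Genome positions were not used here.

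Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with defaults, 1 mean per group, two-sided). All 23 arrays shared 1 estimate of the spread, and p was adjusted by Benjamini-Hochberg over the kept probe sets with a threshold of 0.05. The 8 comparisons were H2S against air at 24 h and at 144 h, H2S at 3 h and 6 h against air at 24 h, air at 144 h against air at 24 h, the difference between the exposure effects at 144 h and 24 h, and the steps from 3 h to 6 h and from 6 h to 24 h among exposed animals. The comparisons at 3 h, 6 h and 24 h share their air animals, so their calls were not set against each other. Nothing in the labels pairs animals.

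Gene lists, 25 in all, were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation beside it. The p was adjusted over the lists of a comparison. Limma's fry was also run, and its values are not given here. The calls that hold with an estimated correlation are those of the NRF2 list at 3 h, the immediate-early list from 3 h to 6 h, and the cell cycle and secretory lists from 6 h to 24 h. Counts of members are given over all probe sets and adjusted over the list alone. The lists cover NRF2 targets, heat shock, immediate-early, unfolded protein, p53, cytokine, interferon, repair, cell cycle, glycolysis, sulfide oxidation, complex IV, other respiratory chain, xenobiotic metabolism, ribosomal protein and squamous genes, and markers of basal, ciliated, secretory, nasal gland, olfactory, leukocyte, stroma and vessel, blood, and cartilage and bone cells. The level of a list in an animal is the mean log2 value of its members minus the mean of all genes of that array, and levels, 3' to 5' ratios and array medians were compared by exact permutation tests, two-sided. These exact p values were not adjusted over lists or comparisons. They also depend on the group sizes, so values with and without an animal are not directly comparable.

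The other settings were fixed before the data were examined, except those without animals 18 and 22 and the fit of the 19 arrays with an RNA integrity number and no covariate. So were the lists, the comparisons, the filter and the rule for named genes. By that rule, genes past the threshold were named where they had 1 symbol, represented their gene and did not overlap between groups, up to 12 in each direction against air and 6 in the other comparisons. Up to 4 members of a list past its threshold with the largest change, or the 2 with the smallest p, were named as well. Where no probe set passed, the 10 genes with the smallest p were given as values. Krt5, Foxj1, Muc5ac, Mki67, Hmox1, Cdkn1a, Il1b and Sqor were allowed in any comparison as values.

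Results were also computed with other settings, chosen with the comparisons. These were pseudocounts of 1 and 64, quantile normalization, median centring, no filter, a filter at the 75th percentile, trend and robust options, array weights, the RNA integrity number as a covariate, leaving out arrays with a number under 3, fitting only the groups compared, leaving out animals 6, 14 and 18, the mean of all probe sets of a gene, an estimated correlation, and leaving out each animal in turn. Leaving out animals 18 and 22, with and without the array median as a covariate, was added after the data were seen, and kept 19036 probe sets. A fit of the 19 arrays with an RNA integrity number, the ones used with that covariate, was also added then without the covariate. Tests of array quality at 3 h and 6 h were added then as well. List tests were repeated with quantile normalization, the mean of all probe sets of a gene and an estimated correlation. They were also repeated without each animal and in both settings without animals 18 and 22. List tests were not run with the remaining settings, such as the RNA integrity covariate or array weights. Animals 6, 14 and 18 carry a treatment field that names 5 repeat days although their group is a single exposure, and the group was used. The labels give an age of 60 days where the design text gives 10 weeks, and the design text names 24 rats. The RNA integrity number is given for 19 arrays.

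The analysis was tested on simulated data with equal noise on all arrays and 50 probe sets changed at each of 4 sizes. In the 24 h comparison, 12% of log2 changes of 1, 44% of 2, 78% of 3 and 98% of 4 were recovered, with 2 false calls. With the 21 arrays left without animals 18 and 22, the shares were 18%, 72%, 84% and 96%, with 10 false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.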

Results

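Expression was measured on 23 Affymetrix Rat230_2 arrays, each holding RNA of a single male Sprague-Dawley rat. The RNA came from nasal respiratory epithelium that was laser captured at the site of injury and regeneration after nose-only exposure to hydrogen sulfide (H2S), a toxic gas that inhibits the mitochondrial respiratory chain, or to air. Animals breathed 200 ppm H2S for 3 h and were sampled 3 h (n = 4), 6 h (n = 3) or 24 h (n = 4) after the initial exposure, or breathed it for 3 h on each of 5 consecutive days and were sampled at 144 h (n = 4). Air animals were sampled at 24 h (n = 4) and 144 h (n = 4), so the groups at 3 h and 6 h were set against air animals of 24 h and differ from them in time as well as in exposure. Changes are on the log2 scale of the signal plus 16, with the standard error (SE) of the fitted model, and levels are means ± SD over animals. This scale understates the change of genes with low signals. No detection calls were at hand, so where a group mean lay under 6, a signal of 48, the size of a change rests on the pseudocount, and such genes are named in each part. Of 31099 probe sets, 19822 were kept and tested. With no change, a share of about 0.05 of these would have an unadjusted p under 0.05, so counts at that p are not calls. The counts of 834 from 3 h to 6 h and 607 from 6 h to 24 h lie under that share. So does the 929 for the difference between the exposure effects at 144 h and 24 h. The number of arrays limits the precision, and the median SE of a change was 0.485 for 4 animals against 4.

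Arrays of 2 air animals stood apart from the other 21. The array of animal 18 (air, 24 h) had a median correlation of 0.408 with the other arrays and a spike-in control signal 161 times that of the median array. The array of animal 22 (air, 144 h) had a median correlation of 0.685 and a spike-in signal 34.2 times that of the median array. Both stayed in the comparisons, and values without them, a setting chosen after the data were seen, are given beside each count. Neither ratio of 3' to 5' signal differed detectably between exposed and air animals at 24 h or 144 h: the log2 ratio of Gapdh was 2.91 against 2.65 at 24 h (exact permutation p = 0.8, two-sided) and 2.59 against 1.97 at 144 h (exact p = 0.143), and that of beta-actin 6.36 against 5.22 at 24 h (exact p = 0.114) and 4.84 against 5.19 at 144 h (exact p = 0.857). The log2 array median was 7.30 in H2S and 7.58 in air animals at 24 h (exact p = 0.457) and 7.25 and 7.62 at 144 h (exact p = 0.0571), where 0.0286 is the smallest p that 4 animals against 4 can give. RNA integrity numbers at 144 h were 4.8, 5.1, 4.5 and 1.7 in H2S animals and 5.6, 6.4, 5.1 and 6.9 in air animals. No exposed animal thus exceeded any air animal, so exposure and RNA integrity are hard to tell apart at 144 h. List tests were not run with the number as a covariate. Tests of the 3 h and 6 h groups against air animals of 24 h, added after the data were seen, gave exact p of 0.886 and 1 for Gapdh, 0.4 and 0.457 for beta-actin, and 0.686 and 0.657 for the array median.

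**Figure D1:**
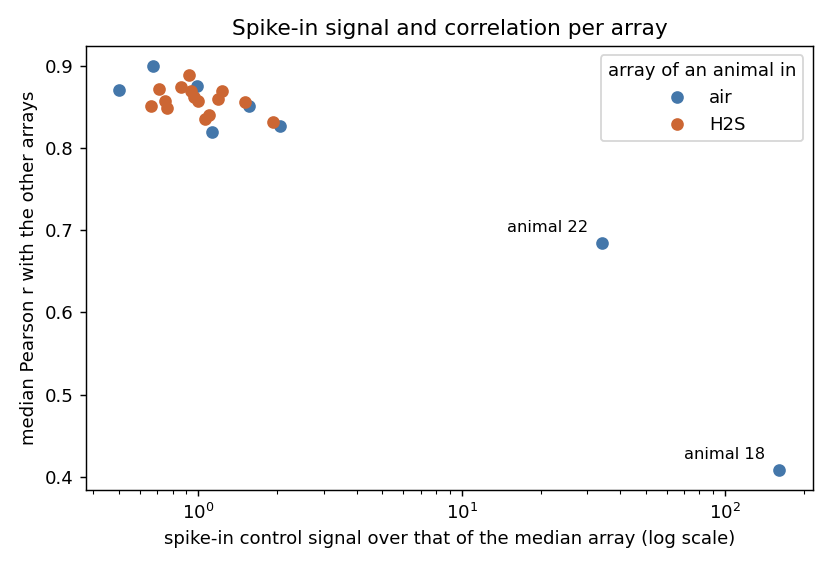
Each point is the array of 1 animal, with the spike-in control signal over that of the median array on the x axis (log scale) and the median Pearson correlation with the other arrays on the y axis, in orange for H2S and blue for air. Animals 18 (161 times, 0.408) and 22 (34.2 times, 0.685) lie apart from the other 21 arrays.

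At 3 h after the initial exposure, against air animals of 24 h, limma called 16 probe sets. Atf3, a transcription factor induced by cellular stress, rose by 3.38 (SE 0.489, adjusted p = 0.00649), from 8.37 ± 0.442 in 4 air animals to 11.75 ± 1.22 in 4 exposed animals. Fosl1, a member of the AP-1 transcription factor family, rose by 3.42 (SE 0.521, adjusted p = 0.00649), and Pvr, an adhesion receptor, by 2.65 (SE 0.397, adjusted p = 0.00649). Akr1b8, an aldo-keto reductase, rose by 3.89 (SE 0.727, adjusted p = 0.0401), Mt2A, a metallothionein, by 2.91 (SE 0.508, adjusted p = 0.0222), and Hspa1a, an inducible heat shock protein, by 2.88 (SE 0.562, adjusted p = 0.0472). Further rises were those of the matrix metalloproteinase Mmp3 (3.56), the TNF receptor family member Tnfrsf12a (3.25), Zfand2a (2.40), the adenosine receptor Adora2b (2.38) and Mrto4 (2.34), with adjusted p from 0.0181 to 0.0419. A second probe set of Mrto4 changed by -0.0995. Spetex2l2 fell by 3.11 (SE 0.586, adjusted p = 0.0401). Low group means were those of Spetex2l2 in exposed animals (-3.88 with a pseudocount of 1, adjusted p = 0.0539, and -2.13 with 64) and Fosl1 in air animals (3.88 and 2.63). Each of these genes had no overlap between the 4 exposed and the 4 air animals. Of the 16, 14 rose and 2 fell, and 1942 had an unadjusted p under 0.05. Outside the rule for named genes, and so named after their values were seen, were a second probe set of the chaperone Dnajb1, which rose by 3.07 (adjusted p = 0.00649), and 3 probe sets with no single gene symbol. Of these, 1 rose by 2.81, 1 rose by 3.23 and 1, with a low mean in exposed animals, fell by 2.82 (-4.32 with a pseudocount of 1 and -1.61 with 64). Without animals 18 and 22, 21 probe sets rose and 3 fell, 14 of them shared with the 16, and the changes of Mmp3 (3.13, adjusted p = 0.108) and Spetex2l2 (-2.75, adjusted p = 0.065) no longer passed. Leaving out 1 animal at a time gave 14 probe sets without animal 3, 20 without 4, 5 without 5, 5 without 6, 12 without 15, 3 without 16, 10 without 17 and 16 without 18; Atf3 and Pvr passed in all 8 cases, Fosl1 in all but the case without animal 16, and the other genes that the rule named lost their calls in 3 to 7 of the 8. Without animals 5, 6, 9 and 15, which have no RNA integrity number, limma called 0 probe sets, both with the number as a covariate (Atf3 2.65, adjusted p = 0.379) and, in a fit chosen after the data were seen, without it (2.81, adjusted p = 0.0928). It also called 0 with only the 2 groups fitted, 9 with a pseudocount of 1, 8 with no filter, 8 without animals 6, 14 and 18, whose exposure label is in doubt, and 67 with array weights. Without animals 18 and 22 and with the array median as a covariate it called 32.

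**Figure D2:**
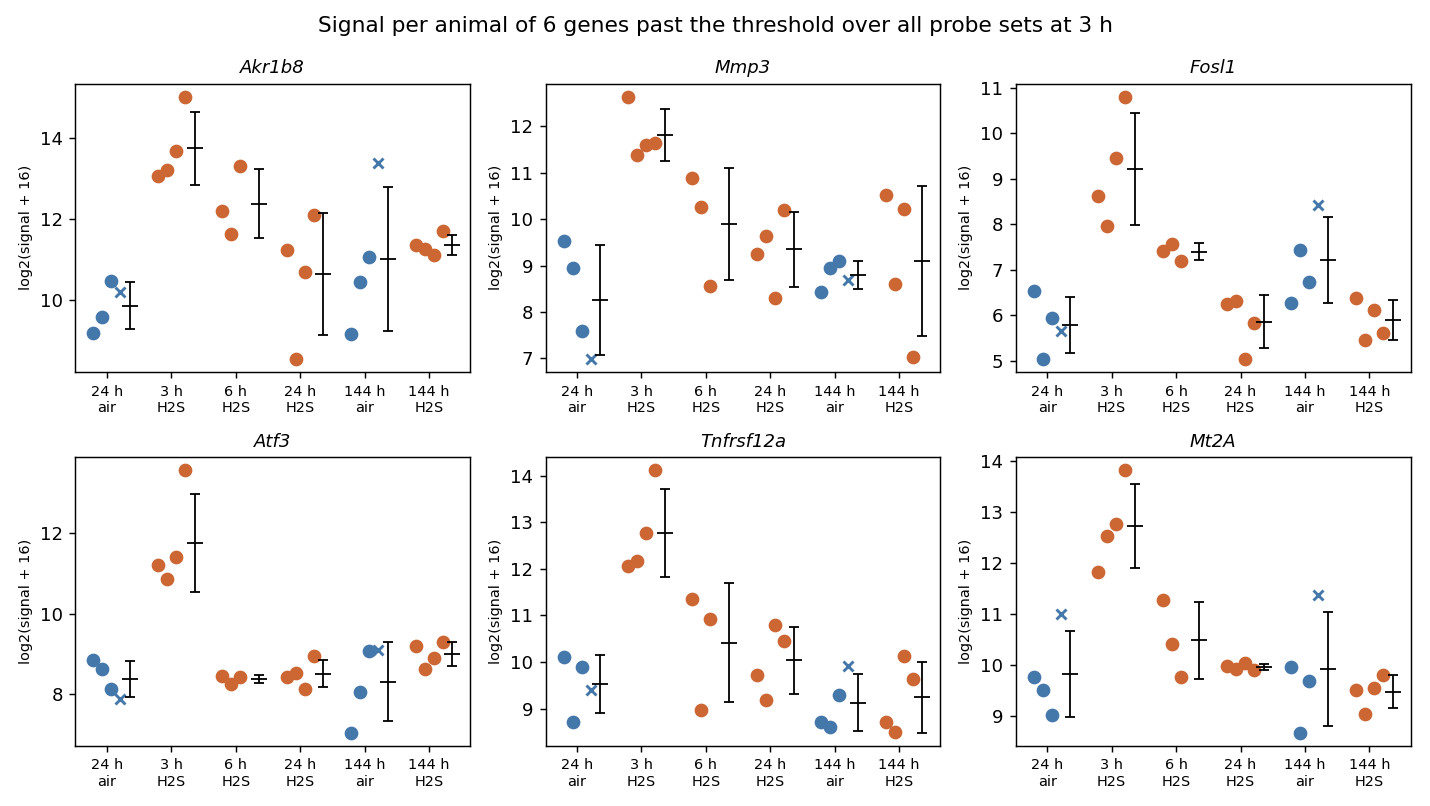
Each point is the log2 of the signal plus 16 (y axis) of 1 animal in the 6 groups (x axis), for the 6 genes with the largest rise at 3 h among those that the rule named past the threshold over all probe sets; orange is H2S, blue is air, crosses are animals 18 and 22, and bars are mean ± SD of all animals. Atf3 was 11.75 ± 1.22 at 3 h and 8.38 ± 0.11 at 6 h.

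The largest shifts among the gene lists at 3 h were those of the cytoprotective lists. Of 19 measured NRF2 targets and glutathione genes, which serve defence against oxidants, 18 had higher values, 8 rose when adjusted over the list alone and 2 when adjusted over all probe sets. The median change was 1.14 (camera adjusted p = 1.41e-08, and adjusted p = 0.0472 with an estimated correlation). Its largest risers were Akr1b8, the heme oxygenase Hmox1 (3.06, SE 0.675), Mt2A and the glutathione synthetase Gss (2.29, SE 0.586). Hmox1 missed the threshold over all probe sets with all arrays (adjusted p = 0.0991) and passed without animals 18 and 22 (3.84, adjusted p = 0.00517). The level of the list, relative to the mean of all genes of the array, was 1.91 ± 0.416 in exposed and 0.641 ± 0.353 in air animals (exact p = 0.0286). All 12 heat shock and chaperone genes, which refold damaged proteins, had higher values, 8 of them rose when adjusted over the list alone and 1 over all probe sets, and the median was 1.28 (camera adjusted p = 6.89e-08, adjusted p = 0.08 with an estimated correlation). Hspa1a, Hspb1 (2.70, SE 0.656), Hsph1 (1.79, SE 0.474) and Dnajb1 (1.68, SE 0.407) led this list, whose level was 2.81 ± 0.713 against 1.67 ± 0.0741 (exact p = 0.0286, and exact p = 0.0571 without animal 18, where that of the NRF2 list stayed at 0.0286).

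Of 18 immediate-early and early stress genes at 3 h, 5 rose when adjusted over the list alone and 2 over all probe sets, with a median of 0.46 (camera adjusted p = 0.00112, adjusted p = 0.107 with an estimated correlation), led by Fosl1, Atf3, Fosb (2.54, SE 0.614) and Maff (1.49, SE 0.541). Of 21 genes of epithelial repair, EGFR ligands and matrix remodelling, 4 rose when adjusted over the list alone and 0 by limma over all probe sets, with a median of 0.86 (camera adjusted p = 0.00202, adjusted p = 0.128 with an estimated correlation). These were the serpin Serpinb2 (4.82, SE 1.68), the keratin Krt17 (3.43, SE 0.942), the annexin Anxa1 (1.99, SE 0.559) and the plasminogen activator Plat (1.46, SE 0.437). Serpinb2 had a low mean in air animals, and its change was 6.67 with a pseudocount of 1 and 3.53 with 64. The median of the immediate-early list was 0.30 without animal 6 and 0.71 without animal 15, and that of the repair list 0.57 without animal 18, with both calls kept.

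Other lists were called at 3 h only with certain animals in. Leukocyte markers had a median of 0.65 (26 of 29 positive, camera adjusted p = 0.00435, adjusted p = 0.573 with an estimated correlation), with 2 members, Slpi (2.46, SE 0.656) and Cd14 (2.35, SE 0.684), past the threshold adjusted over the list alone. Without animal 4 (0.37), 16 (0.69) or 17 (0.62) the call ended, and the median was 0.98 without 15. Cd14 changed by 1.46 without animals 18 and 22, and 0 members then passed over the list alone. Interferon response genes had a median of 0.72 (13 of 15 positive, camera adjusted p = 0.00435, adjusted p = 0.481 with an estimated correlation), with Rsad2 (2.52) and Ifit3 (1.86) past the threshold over the list alone. Without animal 5 (0.52), 16 (0.47) or 17 (0.65) the call ended. Ciliated cell markers had a median of 0.73 (25 of 28 positive, camera adjusted p = 0.00435, adjusted p = 0.713 with an estimated correlation), with Drc1 at 1.77 and Mlf1 at 1.53. Without animal 6 (0.60) or 15 (0.50) the call ended, and Drc1 changed by 0.95 without animals 18 and 22. Genes of the unfolded protein and integrated stress response had a median of 0.56 (16 of 19 positive, camera adjusted p = 0.0401, adjusted p = 0.481 with an estimated correlation), with 1 member, the transcription factor Ddit3 (1.91, SE 0.497), past the threshold over the list alone. The list lost its call with quantile normalization (0.45) and without animal 3 (0.46), 5 (0.47), 6 (0.30), 15 (0.39), 16 (0.37) or 17 (0.53), and Ddit3 changed by 1.19 without animals 18 and 22. Olfactory epithelium markers had a median of -0.48 (3 of 13 positive, camera adjusted p = 0.00768, adjusted p = 0.107 with an estimated correlation), with the cytochrome P450 Cyp2a3 at -1.15 and the neuronal tubulin Tubb3 at -1.63. Without animal 18 (-0.26) and without animals 18 and 22 (-0.26) the call ended, and without both Tubb3 changed by -0.77. Tubb3 had a low mean in exposed animals (-2.28 with a pseudocount of 1 and -1.01 with 64). The median was -0.98 without 15 and -0.77 without 16. Among the other 16 lists, the smallest camera adjusted p was 0.0516.

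**Figure D3:**
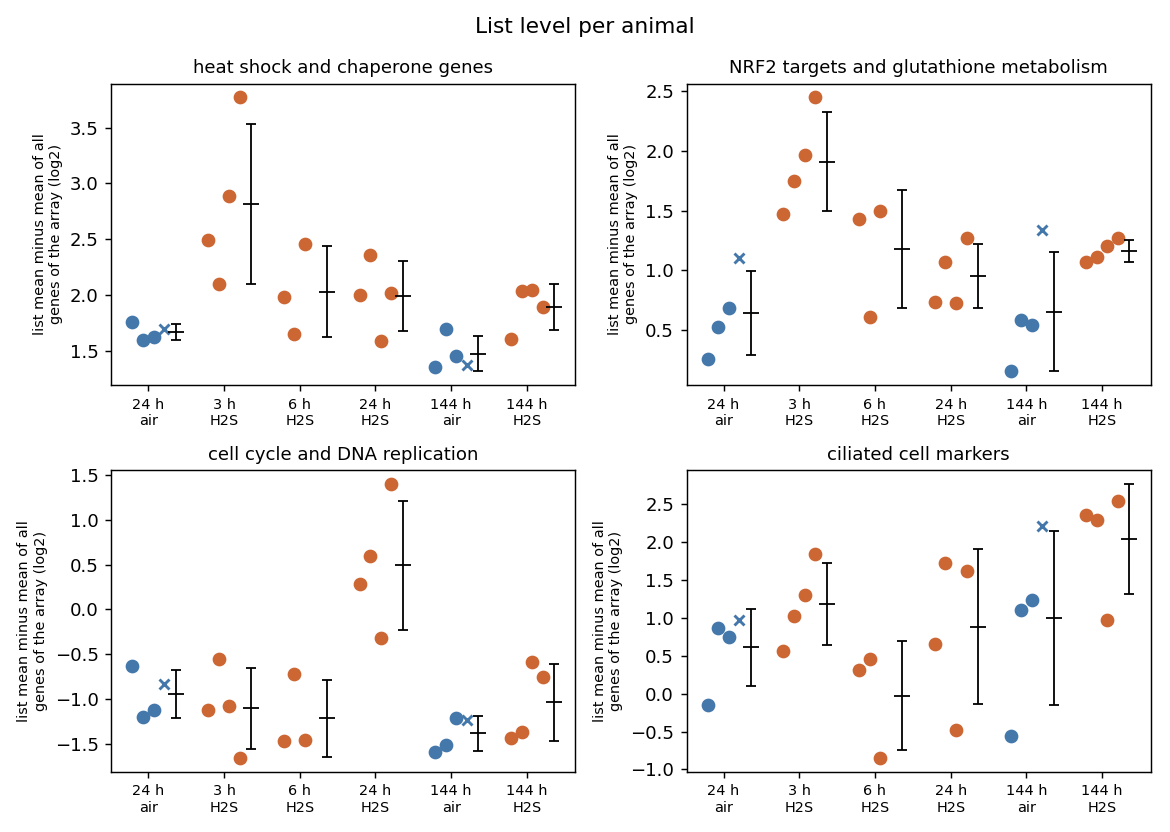
Each point is the mean log2 value of a list minus the mean of all genes of the same array (y axis) for 1 animal in the 6 groups (x axis); orange is H2S, blue is air, crosses are animals 18 and 22, and bars are mean ± SD of all animals. The NRF2 list was at 1.91 ± 0.416 at 3 h against 0.641 ± 0.353 in air at 24 h, and the cell cycle list at 0.492 ± 0.719 against -0.945 ± 0.264 at 24 h.

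At 6 h after the initial exposure, limma called 1 probe set against air animals of 24 h, and 1151 had an unadjusted p under 0.05. It was a probe set of Fam81a, which fell by 3.67 (adjusted p = 0.0174), and it lies outside the rule for named genes and is named after its value was seen. Its mean in exposed animals was low, and the change was -4.17 with a pseudocount of 1 and -2.85 with 64. Its other probe sets changed by -1.06 and -1.60. Ciliated cell markers were lower in 3 exposed than in 4 air animals: 3 of 28 had positive changes and the median was -0.58 (camera adjusted p = 0.000977, adjusted p = 0.788 with an estimated correlation). The members with the smallest p were Efhc2 (-1.81, SE 0.84) and the dynein Dnah2 (-1.48, SE 0.813), neither past the threshold. Among preset genes, Hmox1 changed by 1.04 (SE 0.729, adjusted p = 0.781) and the mucin Muc5ac by -2.90 (SE 1.18, adjusted p = 0.781). The call of the ciliated list ended without animal 10 (-0.073). Hmox1 changed by 1.83 without animals 18 and 22 (adjusted p = 0.891). By limma, 0 probe sets passed without animals 8, 16 or 18 and 11 without animal 9, and without animals 18 and 22 limma called 0 probe sets, with 856 at an unadjusted p under 0.05. It called 68 with array weights and 29 with the RNA integrity number as a covariate, but 0 on the same 19 arrays without that covariate. It called 0 as well with a pseudocount of 64, without numbers under 3, with only the 2 groups fitted, and without animals 6, 14 and 18. No other list was called, and the smallest camera adjusted p of the other 24 was 0.0503.

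From 3 h to 6 h among exposed animals, Atf3 fell by 3.38 (SE 0.529, adjusted p = 0.0388), from 11.75 ± 1.22 (n = 4) to 8.38 ± 0.11 (n = 3), and was the single probe set called by limma, with 834 at an unadjusted p under 0.05. Of 18 immediate-early genes, 3 had positive changes, and Atf3 and Fosl1 (-1.82, SE 0.563) fell when adjusted over the list alone. The median was -0.74 (camera adjusted p = 4.76e-07, and adjusted p = 0.0351 with an estimated correlation, which was 0.177 without animals 18 and 22), and the exact p of the list levels was 0.0571. The median of 12 heat shock genes was -0.61 (camera adjusted p = 1.69e-05, adjusted p = 0.179 with an estimated correlation; -0.30 without animal 6), with Hspa1a (-2.29, SE 0.607) past the threshold over the list alone. All 28 ciliated cell markers had lower values at 6 h, with a median of -1.25 (camera adjusted p = 1.15e-15, adjusted p = 0.311 with an estimated correlation), a list level of -0.0238 ± 0.719 against 1.19 ± 0.54 (exact p = 0.0571), and Rsph9 (-1.79) and Tekt4 (-1.86) as the members with the smallest p. That median was -0.82 without animal 10. Without animals 18 and 22, which count toward the shared spread, 2 probe sets rose and 1 fell, 1 of them shared. Atf3 lost its call without animal 3, 5, 6, 8 or 10, each of which left 0 probe sets by limma, and 31 probe sets passed without animal 9. Limma also called 0 with quantile normalization, median centring, no filter, or only the 2 groups fitted, but 110 with array weights and 14 with the RNA integrity number as a covariate (4 on the same arrays without it).

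Further lists moved from 3 h to 6 h, each with a call that single animals ended. NRF2 targets had a median of -0.82 (2 of 19 positive, camera adjusted p = 2.51e-05, adjusted p = 0.178 with an estimated correlation), with Mt2A (-2.25, SE 0.549) past the threshold over the list alone. Without animal 9 (-0.50) the call ended. Leukocyte markers had a median of -0.67 (1 of 29 positive, camera adjusted p = 0.000475, adjusted p = 0.409 with an estimated correlation), with Cd3g at -1.30 and Itgb2 at -0.97. Without animal 4 (-0.41), 8 (-0.39) or 10 (-0.25) the call ended, and the median was -1.31 without 9. Repair genes had a median of -0.63 (4 of 21 positive, camera adjusted p = 0.0139, adjusted p = 0.311 with an estimated correlation), with Plat at -1.20 and Krt17 at -2.06. Without animal 6 (-0.37) or 9 (-0.52) the call ended. Secretory and goblet cell markers had a median of -0.36 (6 of 21 positive, camera adjusted p = 0.0193, adjusted p = 0.36 with an estimated correlation), with Bpifb1 (-3.72, SE 0.997) and the mucin Muc5b (-2.52, SE 0.752) past the threshold over the list alone. Without animal 6 (-0.16) or 8 (-0.21) the call ended, and the median was -0.57 without 10. Cartilage and bone markers had a median of 0.80 (8 of 11 positive, camera adjusted p = 0.0193, adjusted p = 0.36 with an estimated correlation), with the collagen Col11a1 at 1.36 and Dmp1 at 0.89. Without animal 3 (0.66), 5 (0.63), 8 (0.62) or 9 (0.53) and without animals 18 and 22 (0.81) the call ended, and the median was 1.22 without 4. Stress response genes of the unfolded protein list had a median of -0.26 (4 of 19 positive, camera adjusted p = 0.0328, adjusted p = 0.36 with an estimated correlation), with Atf4 at -0.77 and Sesn2 at -0.66. Without animal 3 (-0.31), 5 (-0.27), 6 (-0.36) or 9 (-0.30) the call ended, and the median was -0.55 without 4, -0.49 without 8 and -0.40 without 10. Among the other 16 lists, the smallest camera adjusted p was 0.125.

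At 24 h, against air animals of the same time, genes of cell division were higher after H2S. Of 50 measured cell cycle and DNA replication genes, 48 had higher values and 34 rose when adjusted over the list alone, and 0 by limma over all probe sets. The median change was 1.64 (camera adjusted p = 6.06e-27, adjusted p = 0.06 with an estimated correlation). The largest risers past the threshold over the list alone were the mitotic kinesin Kif20a (3.15, SE 0.712), the cyclin Ccna2 (3.01, SE 0.744), the cyclin-dependent kinase Cdk1 (2.92, SE 0.601) and the mitotic kinase Pbk (2.88, SE 0.715). The level of the list was 0.492 ± 0.719 in 4 exposed and -0.945 ± 0.264 in 4 air animals (exact p = 0.0286), and without animal 18 the air level was -0.983 ± 0.309 (n = 3, exact p = 0.0571). The proliferation marker Mki67 changed by 2.06 (SE 0.632, adjusted p = 0.53). Limma called 2 probe sets over all, with 1603 at an unadjusted p under 0.05: the uroplakin-like gene Upk3bl1 rose by 3.60 (SE 0.556, adjusted p = 0.0314), from 5.18 ± 0.603 to 8.78 ± 0.455, and Klra5, a lectin-like receptor of natural killer cells, fell by 3.00 (SE 0.501, adjusted p = 0.0499). Both had a low group mean: with pseudocounts of 1 and 64, the change of Upk3bl1 was 4.44 (adjusted p = 0.142) and 2.51 (adjusted p = 0.00285), and that of Klra5 -4.21 (adjusted p = 0.0709) and -1.90 (adjusted p = 0.117). Without animals 18 and 22, 2 rose and 1 fell, 1 of them shared, with Upk3bl1 at 3.70 (adjusted p = 0.0338) and Klra5 at -2.49 (adjusted p = 0.12). Limma called 0 probe sets without animal 11, 12, 13, 15, 17 or 18, 1 without 14 and 3 without 16; Upk3bl1 lost its call in 7 of the 8 cases and Klra5 in 6. Limma also called 0 with a pseudocount of 1, with no filter, with a filter at the 75th percentile, with trend and robust options, and with only the 2 groups fitted. It called 0 as well without the 4 animals that have no RNA integrity number, with the number as a covariate or without it. With array weights it called 52.

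At 24 h camera called 3 further lists at the preset correlation and none of them with an estimated one. Stroma and vessel markers had a median of -0.30 (11 of 31 positive, camera adjusted p = 0.00501, adjusted p = 0.543 with an estimated correlation), with the matrix protein Sparc at -1.35 and the endothelial claudin Cldn5 at -1.34. Without animal 17 (-0.15) the call ended; the median was -0.20 without 12 and -0.53 without 13, and the exact p of the levels was 0.114. Cldn5 changed by -0.72 without animals 18 and 22. Leukocyte markers had a median of -0.39 (8 of 29 positive, camera adjusted p = 0.0133, adjusted p = 0.556 with an estimated correlation), with Fcgr3a at -1.15 and Lsp1 at -1.21, and the direction turned without animal 15 (0.0063); the median was -0.67 without 18, and the exact p of the levels was 0.114. Immediate-early genes had a median of -0.41 (7 of 18 positive, camera adjusted p = 0.016, adjusted p = 0.543 with an estimated correlation), with Myc at -1.13 and Egr2 at -0.88. Without animal 15 (-0.29) the call ended; the median was -0.20 without 18. None of these members passed the threshold over its list. No other list was called, and the smallest camera adjusted p of the other 21 was 0.0583. Without animals 18 and 22, camera also called basal cell markers (median 1.05, adjusted p = 9.14e-05), NRF2 targets (0.46, adjusted p = 0.00414), secretory markers (0.39, adjusted p = 0.00767), xenobiotic metabolism genes (0.39, adjusted p = 0.00767) and ciliated markers (0.43, adjusted p = 0.0364). With an estimated correlation, their adjusted p ran from 0.352 to 0.748.

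From 6 h to 24 h among exposed animals, cell cycle genes rose. Of 50 members, 49 had higher values, 32 rose when adjusted over the list alone and 1 over all probe sets, with a median of 1.66 (camera adjusted p = 5.38e-51, and adjusted p = 0.0032 with an estimated correlation, which was 0.0521 without animals 18 and 22). The list level was 0.492 ± 0.719 (n = 4) against -1.22 ± 0.428 (n = 3, exact p = 0.0571). The member past the threshold over all probe sets was Racgap1, which serves in cytokinesis and rose by 2.64 (SE 0.439, adjusted p = 0.0461), and the largest risers over the list alone were the spindle checkpoint kinase Ttk (3.47, SE 0.881), the cytokinesis factor Ect2 (3.30, SE 0.675), Ccna2 (3.15, SE 0.803) and Pbk (3.14, SE 0.772). At 6 h the means of Ttk (4.16 with a pseudocount of 1 and 2.57 with 64) and of Fam81a (3.87 and 2.58) were low. Secretory and goblet cell markers were also higher, 20 of 21, with a median of 0.69 (camera adjusted p = 4.92e-07, and adjusted p = 0.0385 with an estimated correlation, which was 0.0882 without animals 18 and 22) and a level of 1.66 ± 0.25 against 0.768 ± 0.27 (exact p = 0.0286). The members with the smallest p were Muc5b (2.32, SE 0.752) and the mucin-folding protein Agr2 (1.93, SE 0.647), neither past the threshold. Limma called 2 probe sets, Racgap1 and the Fam81a probe set (3.39, adjusted p = 0.0461, named after its value was seen), with 607 at an unadjusted p under 0.05, and 4 without animals 18 and 22, 2 of them shared. Camera called 5 other lists of cell type markers in this comparison, none with an estimated correlation. The medians were 0.99 for ciliated (adjusted p = 0.249 with an estimated correlation), -0.44 for leukocyte (0.336), -0.55 for stroma and vessel (0.0753), -0.76 for cartilage and bone (0.14) and -0.61 for blood cell markers (0.0607). Levels of the last 3 at 24 h and 6 h were 1.18 ± 0.396 and 1.77 ± 0.341 (exact p = 0.114), 0.011 ± 0.471 and 0.982 ± 0.074 (exact p = 0.0571), and -1.23 ± 0.198 and -0.387 ± 0.0293 (exact p = 0.0286). The direction of the leukocyte median turned without animal 9. Falls of these non-epithelial lists beside rises of ciliated and secretory markers could also come from a different share of epithelium in the captures. That was not tested for this comparison, and it stays open for the cell cycle rise as well. Limma called 0 probe sets without animal 8, 9, 10, 11 or 14, 1 without 12 and 9 without 13; Racgap1 kept its call in the case without 13. Limma also called 0 with no filter, with only the 2 groups fitted, and without animals 6, 14 and 18, but 93 with array weights and 31 without RNA integrity numbers under 3.

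At 144 h, after 5 daily exposures, ciliated cell markers were higher in H2S than in air animals of the same time. All 28 measured markers had positive changes, with a median of 1.10 (camera adjusted p = 4.71e-09, adjusted p = 0.468 with an estimated correlation), and 0 passed limma when adjusted over the list alone or over all probe sets. The members with the smallest p were the ciliogenesis factor Rfx3 (1.39, SE 0.46) and Ropn1l (1.62, SE 0.569). The list level was 2.05 ± 0.723 in 4 exposed and 0.999 ± 1.15 in 4 air animals, a difference within the spread between animals (exact p = 0.2). The median was 0.64 without animal 19 and 1.51 without animals 18 and 22, when 18 markers passed over the list alone. Cartilage and bone markers were lower, 1 of 11 positive, with a median of -1.59 (camera adjusted p = 0.000188, adjusted p = 0.464 with an estimated correlation). The members that fell when adjusted over the list alone were the collagens Col10a1 (-4.15, SE 1.54) and Col2a1 (-2.76, SE 1.07), Comp (-2.29, SE 0.828) and Chad (-1.96, SE 0.599), where Col10a1 had a low mean in exposed animals (-4.88 with a pseudocount of 1 and -3.34 with 64). The cartilage level was 0.0081 ± 0.312 in exposed and 1.53 ± 1.26 in air animals (exact p = 0.114), and the median was -0.88 without animal 19 and -0.86 without animals 18 and 22 and with the array median as a covariate. Limma called 0 probe sets over all, with 1546 at an unadjusted p under 0.05, and 1 without animals 18 and 22, with 2404 at that p; it called 2 without animal 20. The 10 genes with the smallest p were the chromatin assembly factor subunit Chaf1a (2.21), Tmem43 (1.67), Lrrc38 (-2.04), the collagen Col9a3 (-2.94), Akap14 (2.23), the ciliary kinesin Kif3a (1.90), Fsd1 (-2.11), Rnf227 (1.98), Myo5b (1.63) and C3h20orf96 (2.51), with adjusted p from 0.258 to 0.58. Chaf1a, Lrrc38 and Fsd1 had a low group mean.

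Squamous differentiation genes at 144 h had a median of 1.23 (9 of 10 positive, camera adjusted p = 0.00228, adjusted p = 0.468 with an estimated correlation), with Sfn at 2.13 and the desmosomal Dsp at 1.40, but animal 25 alone was at a list level of 3.26 where the other exposed animals were between -1.64 and -1.26. Without it (0.094) the call ended. Stroma and vessel markers had a median of -0.61 (6 of 31 positive, camera adjusted p = 0.0022, adjusted p = 0.464 with an estimated correlation), with Col6a1 at -0.996 and Tie1 at -1.08, and the median was -0.40 without animal 21, -0.34 with quantile normalization, and -0.20 with the call lost without animals 18 and 22 and with the array median as a covariate. Col6a1 changed by -0.59 without both animals. NRF2 targets had a median of 0.48 (16 of 19 positive, camera adjusted p = 0.0131, adjusted p = 0.464 with an estimated correlation), with the cystine transporter Slc7a11 at 1.90 and the quinone reductase Nqo1 at 1.42. Without animal 19 (0.35) or 20 (0.48) the call ended, and the median was 0.90 without 22. Cell cycle genes had a median of 0.29 (39 of 50 positive, camera adjusted p = 0.015, adjusted p = 0.603 with an estimated correlation), with Racgap1 at 1.20 and Kif23 at 1.30. Without animal 19 (0.29), 20 (0.31), 25 (0.23) or 26 (0.18) the call ended, and the median was 0.49 without 21, 0.47 without 22, 0.49 without 23, 0.52 without 24 and 0.54 with quantile normalization. Heat shock genes had a median of 0.51 (10 of 12 positive, camera adjusted p = 0.0292, adjusted p = 0.557 with an estimated correlation), with Hspa1a (1.56) and Hsph1 (1.38) higher and the small heat shock protein Cryab lower (-1.72), each past the threshold over the list alone; a second probe set of Hsph1 changed by -0.011. That call ended with quantile normalization (0.42) and without animal 19 (0.55), 21 (0.45), 22 (0.45), 24 (0.54) or 25 (0.36). It also ended without animals 18 and 22 (0.45) and with the array median as a covariate as well (0.15). Xenobiotic metabolism genes had a median of 0.40 (24 of 34 positive, camera adjusted p = 0.0292, adjusted p = 0.588 with an estimated correlation), with Fmo2 at 1.26 and Sult1c2 at 2.12. The list lost its call with quantile normalization (0.46) and without animal 19 (0.32), 20 (0.34), 21 (0.31), 24 (0.32) or 26 (0.26). Glycolysis and hypoxia-response genes had a median of -0.12 (6 of 21 positive, camera adjusted p = 0.0451, adjusted p = 0.562 with an estimated correlation), with the hypoxia-induced hydroxylase Egln3 at -1.54 and the glycolytic enzyme Tpi1 at -0.85. Without animal 19 (-0.37), 21 (-0.19), 22 (-0.37), 23 (-0.15), 24 (-0.20), 25 (-0.20) or both 18 and 22 (-0.37) the call ended, and the median was -0.35 without 20 and -0.22 without 26. Among the other 16 lists, the smallest camera adjusted p was 0.0601.

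The difference between the exposure effects at 144 h and 24 h was tested as an interaction. These times also differ in the number of exposures (5 daily against 1) and in the time since the last one, which cannot be told apart here. Cell cycle genes responded less at 144 h: 4 of 50 had positive differences, with a median of -1.18 (camera adjusted p = 5.12e-12, adjusted p = 0.251 with an estimated correlation), and the thymidine kinase Tk1 (-1.82, SE 0.521) and the topoisomerase Top2a (-2.21, SE 0.745) had the smallest p. Ciliated markers had a median difference of 0.67 (23 of 28 positive, camera adjusted p = 0.00041, adjusted p = 0.603 with an estimated correlation), with Rfx3 at 1.37 and Dnah2 at 2.10. Without animal 13 (0.23) or 19 (0.10) the call ended, and the median was 1.01 without 12, 1.10 without 22 and 1.04 without animals 18 and 22. Cytokine, chemokine and NF-kB target genes had a median of 0.57 (16 of 18 positive, camera adjusted p = 0.00156, adjusted p = 0.153 with an estimated correlation), with the interleukin Il1a at 3.46 and the superoxide dismutase Sod2 at 1.28. Without animal 18 (0.67), 25 (0.25) or animals 18 and 22 (0.67) the call ended, and without both Il1a did not pass the filter. Squamous genes had a median of 1.17 (9 of 10 positive, camera adjusted p = 0.00258, adjusted p = 0.453 with an estimated correlation), with Tgm3 at 2.90 and Dsp at 1.04. Without animal 18 (1.10) or animals 18 and 22 (1.14) the call ended, and the direction turned without animal 25 (-0.025). Tgm3 changed by 1.80 without animals 18 and 22. Glycolysis genes had a median of -0.69 (4 of 21 positive, camera adjusted p = 0.00774, adjusted p = 0.453 with an estimated correlation), with Tpi1 at -1.71 and Egln3 at -1.87. Without animal 13 (-0.55), 18 (-0.41) or animals 18 and 22 (-0.32) the call ended. Targets of p53 and apoptosis genes had a median of 0.45 (9 of 14 positive, camera adjusted p = 0.0349, adjusted p = 0.153 with an estimated correlation), with Sesn1 at 1.02 and Bcl2l11 at 0.73. The list lost its call with the mean of all probe sets of a gene (0.042), without animals 18 and 22 (0.47) and without animal 12 (0.50), 13 (0.39), 18 (0.28), 19 (0.32), 21 (0.44), 23 (0.45) or 25 (0.36). Limma called 0 probe sets, with 929 at an unadjusted p under 0.05, and 0 without animals 18 and 22, with 870. The 10 genes with the smallest p were Zfp385a (-2.38), Upk3bl1 (-3.19), Lrrc38 (-2.64), Mlec (-1.51), Bola3 (-1.78), Acsm3 (2.64), Tmem258 (-1.48), Vch (-2.39), the keratin Krt86 (-2.43) and Pxk (1.83), all at an adjusted p of 0.946. Upk3bl1, Lrrc38, Vch and Il1a had a low group mean. No other list was called, and the smallest camera adjusted p of the other 19 was 0.0638.

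Air animals of 144 h were set against those of 24 h to measure how far the control groups differ. Limma called 0 probe sets, with 1660 at an unadjusted p under 0.05, and 0 without animals 18 and 22, with 861. With all arrays, the 1660 exceeds the counts for H2S against air at 24 h (1603) and at 144 h (1546). Without animals 18 and 22, the 861 lies under theirs (1257 and 2404). Cell cycle genes were lower at 144 h, 17 of 50 positive, with a median of -0.30 (camera adjusted p = 0.00138, adjusted p = 0.912 with an estimated correlation) and with Birc5 (-2.16, SE 0.67) and Ect2 (-1.99, SE 0.624) as the members with the smallest p. That call ended without animal 15 (-0.16), and the median was -0.47 without animal 21. Birc5 changed by -1.25 and Ect2 by -1.17 without animals 18 and 22. The 10 genes with the smallest p were Chaf1a (-2.64), the protease inhibitor Serpina1 (2.08), Timm44 (2.68), the clock gene Npas2 (1.77), LOC102550394 (1.52), Tmem135 (1.19), Mpp2 (1.73), Snrk (-2.24), the urea transporter Slc14a2 (1.54) and Wdtc1 (1.78), with adjusted p from 0.103 to 0.542. Mpp2 changed by 1.04, Snrk by -1.30 and Wdtc1 by 1.06 without animals 18 and 22. Chaf1a, Timm44, Snrk and Birc5 had a low group mean. Chaf1a stood among the smallest p both here and in the exposure comparison at 144 h, which share the 144 h air animals. Among the other 24 lists, the smallest camera adjusted p was 0.0791.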

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

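The tests of the arrays of animals 18 and 22, of lists without these arrays and of the gap to other epithelial lists were chosen only after the results were seen, while the tests with the array median as a covariate and the counts over other splits of the samples were written down before theirs.

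Cell cycle genes were higher in H2S than in air animals at 24 h, with a median change of 1.64 (adjusted p = 0.06 with an estimated correlation, so the call rests on the preset one). The exact p of the list levels was 0.0286, and 0.0571 without animal 18, values of unlike group sizes that were not adjusted over the lists. The arrays of animals 18 and 22 are argued against as its whole cause, since the median was 1.59 without both. A difference in the signal distribution of the arrays is argued against less firmly: the median was 1.59 with the array median as a covariate, but without animal 18 the group medians hardly differed (158 ± 19.7 against 159 ± 21.2), so the covariate had little to remove. A larger share of epithelium in the exposed captures stays open: the gap of the list to the other epithelial lists was -0.65 ± 0.282 in exposed and -1.63 ± 0.663 in air animals, a difference of 0.98 that misses the threshold (exact permutation p = 0.114). Stroma and vessel (-0.30) and leukocyte markers (-0.39) had lower medians in exposed animals, and without animals 18 and 22 basal (1.05), secretory (0.39) and ciliated markers (0.43) were called as higher. None of the 5 calls held with an estimated correlation (adjusted p from 0.352 to 0.748), and the leukocyte direction turned without animal 15. More dividing cells at the site 24 h after exposure may account for it as a biological hypothesis, which was not tested apart from these values.

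Ciliated cell markers were higher in H2S than in air animals at 144 h, with a median change of 1.10 (adjusted p = 0.468 with an estimated correlation, so the call rests on the preset one). The median was 0.64 without animal 19, and the exact p of the list levels was 0.2. The arrays of animals 18 and 22 and the signal distribution are argued against as its whole cause, since the median was 1.51 without both arrays and 1.66 with the array median as a covariate as well. A larger share of epithelium in the exposed captures stays open: the gap of the list to the other epithelial lists was 0.76 ± 1.09 in exposed and 0.044 ± 0.562 in air animals, a difference of 0.71 that did not exceed the spread (exact permutation p = 0.371). Stroma and vessel markers (-0.61) and cartilage and bone markers (-1.59) had lower medians in the same exposed animals, as such a share would need, but neither call held with an estimated correlation (adjusted p = 0.464 for both). The stroma median was -0.20, with its call lost, without animals 18 and 22 and with the covariate. The cartilage median was -0.88 without animal 19, and the exact p of its levels was 0.114. The RNA integrity numbers of the exposed animals (4.8, 5.1, 4.5 and 1.7) did not exceed those of the air animals (5.6, 6.4, 5.1 and 6.9). A difference in RNA integrity stays open too, since list tests were not run with the number as a covariate. A renewal of ciliated cells after 5 daily exposures is a biological hypothesis that the design allows and that was not tested.

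The arrays of animals 18 and 22 stood apart from the other arrays. Little labelled target on the array stays open. The spike-in controls, added in a fixed amount, read 161 and 34.2 times the median array, against at most 2.04 on the other arrays. These values were read from arrays whose trimmed means all lie at about 500, so they are relative to the rest of the array. They are part of what sets the 2 arrays apart, so they do not test that explanation. Low RNA integrity is argued against as the whole cause for animal 18: its number was 2.6, and the other arrays with a number as low had median correlations of at least 0.856. The number of animal 22 was 0.971 SD above the median of 5.1, which neither excludes nor favours RNA quality. No biological explanation was tested.

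Of 128 groups tested for a single animal far from the others, 15 held one. Chance alone gives about 1 in 20 for independent, normally distributed values, while many of these values came from the same arrays. Only groups of 4 values with none missing were tested. The 6 h group (n = 3) and RNA integrity numbers in groups with a missing one were thus left out. For animal 18 among air animals of 24 h, the values were a median correlation of 0.408 (others 0.852 to 0.9), a spike-in signal of 161 times (0.502 to 1.56), a p53 list level of 0.433 (-0.268 to -0.182), a squamous list level of 0.364 (-1.59 to -1.40), a log2 value of Zfand2a of 9.98 (8.55 to 8.77) and of Adora2b of 9.59 (7.18 to 7.28). For animal 22 among air animals of 144 h, the values were a spike-in signal of 34.2 times (0.986 to 2.04), a Gapdh ratio of 3' to 5' signal of 7.74 (2.68 to 3.52) and a ratio of 2.12 in the labels, whose meaning is not given in the sources used here (1.82 to 1.86). Animal 25 among H2S animals of 144 h had a squamous list level of 3.26 (-1.64 to -1.26), a cartilage list level of -0.459 (0.145 to 0.173) and a ciliated list level of 0.972 (2.30 to 2.55). Animal 14 among H2S animals of 24 h had a p53 list level of -0.122 (-0.329 to -0.295), and animal 12 a beta-actin ratio of 3' to 5' signal of 199 (56.4 to 65.7). Animal 4 among H2S animals of 3 h had an unfolded protein list level of 0.959 (1.52 to 1.6).

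The exposure effect differed between 144 h and 24 h, times that also differ in the number of exposures, by camera on the interaction, for 6 lists. The median differences were -1.18 for cell cycle genes, 0.668 for ciliated markers, 0.57 for cytokine genes, -0.694 for glycolysis genes, 0.451 for p53 targets and 1.17 for squamous genes. None of the 6 passed with an estimated correlation, where the adjusted p ran from 0.153 to 0.603. The squamous difference turned without animal 25 (-0.025). Among other cases, calls ended for ciliated markers without animal 13 (0.23) or 19 (0.10), for cytokine genes without animal 25 (0.25), for glycolysis genes without animals 18 and 22 (-0.32) and for p53 targets with the mean of all probe sets of a gene (0.042).

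Other splits of the same animals into groups of the same sizes were counted for each comparison. At 3 h, 16 probe sets passed where the highest other split gave 1, and 1 of 35 splits, the real one, gave as many. That share lies under 5% but is the smallest that 35 splits allow, and it was not adjusted over the 8 comparisons. The count at 3 h was 0 with only the groups compared and on the 19 arrays with an RNA integrity number. The real split also gave more than any other for the 2 at 24 h (highest other 1, 1 of 35) and the 1 from 3 h to 6 h (highest other 0, 1 of 35). These 2 counts lie within 1 of the highest other split and were 0 without single animals in 6 of 8 and 5 of 7 cases, so little rests on them. Chance cannot be excluded at 6 h (1 probe set, highest other 1, 3 of 35 splits) or from 6 h to 24 h (2 probe sets, highest other 70, 4 of 35), nor for counts of 0 at 144 h (highest other 2, 35 of 35), in the interaction (highest other 78, 100 of 100 drawn) and between air groups (highest other 877, 35 of 35), which any split equals. Limma gave 1546, 929 and 1660 probe sets at an unadjusted p under 0.05 in these 3 comparisons, of which the 929 lies under the share that no change would give. The 877 came from a split that set animals 15, 17, 19 and 20 against 16, 18, 21 and 22, which points to a structure of the samples. These 4 and 4 arrays part fully by array median (143 to 174 against 183 to 341) and by spike-in signal (0.502 to 1.13 against 1.56 to 161 times the median array). The split joins animals 18 and 22, as 15 of the 35 splits do; 12 of the 15 gave 0 and the others 3, 90 and 877, so joining them does not by itself account for it. Splits with these 2 animals apart gave at most 2. The 70 probe sets from 6 h to 24 h, from animals 9, 11, 12 and 14 against 8, 10 and 13, point to a structure of the samples as well.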

How the results depend on the processing

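The settings without animals 18 and 22, with and without the array median as a covariate, and the one with only the 19 arrays that have an RNA integrity number were chosen only after the data were seen, and the others were planned. Counts of probe sets by limma were small, and those that moved by over 1.5 times are given here; the cause was not tested, except that settings with fewer arrays or only the groups compared have less information on the spread, and settings without a filter test more probe sets. At 24 h (2 probe sets) the count was 0 with pseudocount 1, no filter, the 75th percentile filter, trend and robust options, the RNA integrity covariate, the same 19 arrays without the covariate and only the groups compared; it was 1 with quantile normalization, without RNA integrity below 3 and without animals labelled 5 repeat days, and 52 with array weights. At 144 h (0) it was 1 with array weights and 1 without animals 18 and 22. At 3 h (16) it was 9 with pseudocount 1, 8 with no filter, 67 with array weights, 0 with the RNA integrity covariate and with the same 19 arrays without it, 0 with only the groups compared, 8 without animals labelled 5 repeat days, and 32 without animals 18 and 22 and with the covariate. At 6 h (1) it was 0 with pseudocount 64, with the 19 arrays and no covariate, without RNA integrity below 3, with only the groups compared, without animals labelled 5 repeat days, and without animals 18 and 22 with or without the covariate, 68 with array weights and 29 with the RNA integrity covariate. From 3 h to 6 h (1) it was 2 with pseudocount 1, 0 with quantile normalization, median centring, no filter and only the groups compared, 110 with array weights, 14 with the RNA integrity covariate, 4 with the 19 arrays and no covariate, 3 without RNA integrity below 3, 2 without animals labelled 5 repeat days, 3 without animals 18 and 22, and 4 with the covariate as well. From 6 h to 24 h (2) it was 1 with pseudocounts 1 and 64 and with median centring, 0 with no filter, with the 19 arrays and no covariate, with only the groups compared and without animals labelled 5 repeat days, 93 with array weights, 31 without RNA integrity below 3, 4 without animals 18 and 22, and 5 with the covariate as well. Leaving out each animal in turn gave 0 to 3 probe sets at 24 h, 0 to 2 at 144 h, 3 to 20 at 3 h, 0 to 11 at 6 h, 0 to 0 between air groups, 0 to 0 in the interaction, 0 to 31 from 3 h to 6 h and 0 to 9 from 6 h to 24 h; the 11 and the 31 were without animal 9 and the 9 without animal 13.

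With an estimated correlation, which leaves a list's median as it is, most list calls ended. Among lists with a median change of at least 1 in size, calls ended for cell cycle genes at 24 h (1.64, adjusted p = 0.06) and in the interaction (-1.18, 0.251). At 144 h they ended for cartilage markers (-1.59, 0.464), ciliated markers (1.10, 0.468) and squamous genes (1.23, 0.468). They also ended for ciliated markers from 3 h to 6 h (-1.25, 0.311), heat shock genes at 3 h (1.28, 0.08) and squamous genes in the interaction (1.17, 0.453). The last was 1.14 without animals 18 and 22 and 0.864 with the covariate as well, past the threshold in neither. Calls with smaller medians ended too, except those of the immediate-early list from 3 h to 6 h and the secretory list from 6 h to 24 h. Leaving out each animal in turn gave medians of 1.32 to 1.81 for cell cycle genes at 24 h, 1.36 to 1.96 from 6 h to 24 h and -1.43 to -0.864 in the interaction, 0.977 to 1.34 for NRF2 targets and 0.923 to 1.49 for heat shock genes at 3 h, -2.36 to -0.88 for cartilage markers and 0.636 to 1.51 for ciliated markers at 144 h, -1.55 to -0.816 for ciliated markers from 3 h to 6 h, 0.0939 to 1.65 for squamous genes at 144 h, and -0.0251 to 1.52 in the interaction. The direction turned in 3 cases: squamous genes in the interaction without animal 25 (-0.0251), leukocyte markers at 24 h without animal 15 (0.00634) and from 6 h to 24 h without animal 9 (0.129). The 2 leukocyte medians ran from -0.673 to 0.00634 and from -0.824 to 0.129. Over settings other than leaving out 1 animal, values of named genes stayed on their side of the threshold in 2249 cases, lost their call in 135 and gained one in 25, and lists kept theirs in 200 and lost theirs in 70. Without 1 animal, these were 1331, 92 and 5 for genes and 374 and 78 for lists. The 2249 and 1331 cases include genes that did not pass with the main settings, where staying uncalled counts as staying. The losses are therefore a larger share of the calls than these totals show. Most of the 70 lost list calls were lost with the estimated correlation. Median centring moved the median of all genes by 0.154 at 24 h, from 0.0727 to 0.227, and by 0.12 at 6 h, from 0.0791 to 0.2; it moved by over 0.1 in no other comparison and under no other scaling. Signals near background limit small changes, as the number of arrays does.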

Other observations

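Several gene groups moved from 6 h to 24 h among exposed animals besides cell cycle and secretory genes, and no member named here passed the threshold over its list except Hbb. Values without animals 18 and 22 come from tests chosen only after the results were seen. A different share of epithelium in the captures at 6 h and 24 h was not tested for these groups and stays open. All 28 ciliated cell markers had higher values, with a median of 0.99 (camera adjusted p = 1.94e-09, adjusted p = 0.249 with an estimated correlation) and 0.53 without animal 10, and Dnah1 (1.20) and Tekt4 (1.30) had the smallest p. Mitochondrial genes were higher: respiratory chain subunits outside complex IV had a median of 0.37 (30 of 32 positive, camera adjusted p = 0.000153, adjusted p = 0.213 with an estimated correlation; 0.16 without animal 9), and subunits of complex IV, the respiratory complex that sulfide inhibits, one of 0.43 (16 of 17 positive, camera adjusted p = 0.00227, adjusted p = 0.0932 with an estimated correlation), with Cox6a1 at 0.91 and Ndufs1 at 0.92. Genes of sulfide oxidation and transsulfuration, which dispose of H2S, had a median of 0.52 (9 of 11 positive, camera adjusted p = 0.00341, adjusted p = 0.0607 with an estimated correlation), with the sulfur transferase Tst at 1.53 and Cdo1 at 1.01. Xenobiotic metabolism genes had a median of 0.29 (27 of 34 positive, camera adjusted p = 0.00341, adjusted p = 0.358 with an estimated correlation), with Cyp2a3 at 1.48 and Aldh1a1 at 0.97; the call ended without animal 9 (0.32) or 14 (0.16), and the median was 0.59 without 10 and 0.57 without 13. Ribosomal protein genes had a median of 0.24 (28 of 30 positive, camera adjusted p = 0.0223, adjusted p = 0.55 with an estimated correlation); the call ended with quantile normalization (0.22) and without animal 8 (0.20), 10 (0.11), 11 (0.20) or 14 (0.17), and the median was 0.42 without 9.

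Lower from 6 h to 24 h were interferon response genes (1 of 15 positive, median -0.76, camera adjusted p = 4.04e-07, adjusted p = 0.0801 with an estimated correlation; -1.27 without animal 8 and -0.50 without 10), with Usp18 at -1.31 and Rsad2 at -1.87. Stroma and vessel markers (2 of 31 positive, median -0.55, camera adjusted p = 3.44e-07, adjusted p = 0.0753 with an estimated correlation; -0.35 without animal 9 and -0.36 without 14) were lower, with Fbn1 at -1.25 and Mgp at -0.81. Cartilage and bone markers had a median of -0.76 (1 of 11 positive, camera adjusted p = 0.0013, adjusted p = 0.14 with an estimated correlation), with Col10a1 at -3.78. The 3 measured blood cell markers had a median of -0.61 (camera adjusted p = 0.00341, adjusted p = 0.0607 with an estimated correlation), and the globin Hbb (-1.36, SE 0.479) passed over the list alone. Cytokine genes had a median of -0.35 (2 of 18 positive, camera adjusted p = 0.00594, adjusted p = 0.0959 with an estimated correlation), with the chemokine Ccl20 at -1.82 and Il1b at -0.81. Immediate-early genes had a median of -0.32 (4 of 18 positive, camera adjusted p = 0.00677, adjusted p = 0.153 with an estimated correlation; -0.17 without animal 10), with Fosl1 at -1.53 (-1.88 with a pseudocount of 1 and -1 with 64, as its mean at 24 h was low). Leukocyte markers had a median of -0.44 (4 of 29 positive, camera adjusted p = 0.00065, adjusted p = 0.336 with an estimated correlation), with S100a8 at -1.88, but 0.13 without animal 9, -0.79 without 8 and -0.82 without 10. The smallest camera adjusted p of the other 10 lists was 0.133.

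Lists of basal cell and nasal gland markers were not called in any of the 8 comparisons with all arrays. Basal cell markers had medians of 0.84 at 24 h (camera adjusted p = 0.0602) and 0.71 at 144 h (camera adjusted p = 0.0741), and without animals 18 and 22 the medians were 1.05 (adjusted p = 9.14e-05, and adjusted p = 0.352 with an estimated correlation) and 1.23 (adjusted p = 0.000969, and adjusted p = 0.354 with an estimated correlation). Krt5, a basal cell keratin, changed by 1.09 (SE 0.95) at 24 h and 1.12 (SE 0.95) at 144 h, and by 1.63 and 1.91 without animals 18 and 22. Nasal gland markers had medians of -0.14 at 24 h (camera adjusted p = 0.469) and -0.66 at 144 h (camera adjusted p = 0.149). Sqor, the mitochondrial enzyme that oxidizes sulfide, changed by 1.24 at 3 h (SE 0.485, adjusted p = 0.433) and 1.46 at 24 h (SE 0.485, adjusted p = 0.575), and by 0.53 and 0.75 without animals 18 and 22. The sulfide oxidation list had medians of 0.66 at 24 h (camera adjusted p = 0.207) and -0.20 at 144 h (camera adjusted p = 0.434) against air. Foxj1, a regulator of motile cilia, changed by 0.045 at 144 h (SE 0.491, adjusted p = 0.99), within its error, and by 0.48 without animals 18 and 22 (SE 0.468, adjusted p = 0.718). Cdkn1a changed by 0.98 at 3 h (SE 0.54, adjusted p = 0.551).

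Without animals 18 and 22, camera called further lists. At 6 h these were NRF2 targets (median 0.69, adjusted p = 2.32e-05), interferon response genes (0.43, adjusted p = 0.000572), basal cell markers (0.86, adjusted p = 0.00177), heat shock genes (0.42, adjusted p = 0.0412) and blood cell markers (0.73, adjusted p = 0.0418), which were higher than in air. Lower at 6 h were respiratory chain subunits outside complex IV (-0.21, adjusted p = 0.00745) and ribosomal protein genes (-0.19, adjusted p = 0.0416). At 3 h, basal cell markers (0.88, adjusted p = 0.000923) and cytokine genes (0.46, adjusted p = 0.00206) were higher and respiratory chain subunits lower (-0.24, adjusted p = 0.0211). At 144 h, genes of the unfolded protein list were lower (-0.43, adjusted p = 0.00568). With an estimated correlation none of these passed, with adjusted p from 0.193 to 0.661.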
